A study of Mus musculus with 2 samples.

How the data were processed

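IRF4 ChIP-seq was made in 2 biological replicates of the mouse B-cell lymphoma line CH12.LX. The labels give 1 group and no treatment; a separate control experiment is named there as a possible control and was not used here. The analysis began from 6 lists of peaks in narrowPeak format. The peak caller, the aligner and the read numbers are not given in the sources used here. The labels number the samples as biological replicates 1 and 2 and say nothing of separate cultures.

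Per the deposited descriptions of the files, the relaxed lists of each replicate and of both replicates pooled were made on mm10 from alignments and 1 further file, and the optimal and conservative IDR lists were made from these lists. The mm9 list was made from the mm9 alignments of both replicates together, with no control named among its inputs. Each peak carries a signal value from the authors' caller, whose scale is not stated. It was used to rank, filter and describe peaks within 1 list, and to set the replicates side by side at matched peaks. A further column of the deposited lists, which the format reserves for a q-value on a log scale, held values below 0 and was treated as a score. The pooled list and the replicate 2 list have exactly 300000 lines each, which was read as a limit on length, while replicate 1 has 215095. The depth per replicate is unknown, and precision is given as Wilson intervals over peaks or as intervals of odds ratios.

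Summits were taken as the start of a peak plus its offset. Coordinates were never converted between builds. The reference sequence and transcripts in use were of mm9 (GENCODE), so motifs and transcript features were analysed on the mm9 list in place of the optimal list that had been planned. Gene starts for the mm10 lists came from RefSeq genes of GRCm38, 1 start per gene, with the strand of the GENCODE gene of the same name on the same chromosome, which gave 20564 of 21631 protein-coding genes a start. The builds were checked by promoter share: 17.5% of mm10 summits lay within 1 kb of these starts, 2.70% within 1 kb of the other gene end, and 4.98% within 1 kb of mm9 gene starts. Alternative starts of a gene are missed on mm10. Peaks on scaffolds were counted in the list sizes and in the comparison of replicates and left out of the location, motif and gene list tests.

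Replicate overlap was the percent of the N strongest peaks of replicate 1 (N being the size of the optimal list) with a summit within 100 bp of one of the N strongest of replicate 2, beside 100 circular shifts of each chromosome. Promoter share was the percent of summits within 1 kb of a gene start, against 10 random positions per peak on the same chromosome; on mm10 these lay between the first and last pooled summit and assembly gaps inside were not left out, for want of the sequence. Strong and weak peaks were the top and bottom quartiles by signal. For 22 motifs, including 4 read backwards as controls, matches on either strand within 50 bp of the summit were compared with windows 300 bp to one side by an exact McNemar test. Peak classes were compared by two-sided Fisher's exact tests. Words of 8 bases and spacings between ETS, IRF and AP-1 sites were counted in the same windows. The 23 gene lists, fixed from textbook knowledge before the data were examined, hold 494 symbols, of which 488 matched a gene; all other protein-coding genes on chromosomes 1 to 19 and X were the background. P-values were adjusted by Benjamini and Hochberg's method within each family, with a threshold of 0.05. Odds ratios with an empty cell had a continuity correction.

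The genes named were set by a rule fixed before the data were examined. It takes the nearest gene of the 10 strongest optimal peaks and every member of the list of IRF4 targets. It takes the 4 members with the strongest peak of each list past the threshold and 2 of each other list. It also takes the 5 genes with most summits and the 10 strong peaks with the largest rank difference between replicates, 5 each way. For the neuron list, which passed in the lower direction, the rule applied likewise. Zbtb20 and Vps8 as host genes, and Cd86, were named after their values were seen. Some genes that the rule takes are not reported here.

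Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, with bedtools 2.31.1 for interval overlaps and samtools 1.23.1 for sequence. The statistics were tested on simulated data. In 44000 simulated peaks with 59.8% shared, 59.9% were recovered. In 27000 simulated windows with EICE set into 7.95%, the excess recovered was 7.93%. For 20000 simulated genes with lists of 25 genes at 90% against 50%, 97.6% of changed lists and 0.667% of unchanged lists were called. All unchanged genes had the same chance there, so the rate does not cover lists that differ in CpG content or gene density. In 14000 simulated peaks with no effect within strata, the stratified odds ratio was 0.997 against a crude value of 0.655.

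Alternatives fixed before the data were examined covered the definition of a shared peak, the number of peaks compared, the promoter distance, the motif window and background, the peak set, each replicate left out, the gene distance and matched random lists. Leaving a replicate out meant taking the N strongest peaks of the relaxed list of the other replicate, without IDR. A further 10 alternatives, among them the stratification by GC content, were chosen after seeing the data. The search over words, the spacing counts, the chromosome comparison and the transcript features were also chosen after seeing the data or without a fixed plan.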

Results

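IRF4 is a transcription factor of the interferon regulatory factor family that acts in germinal centre B cells and plasma cells. Its binding was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in CH12.LX, a mouse B-cell lymphoma line. The samples form 1 group of 2 biological replicates, so each comparison sets peaks against other peaks, against random or neighbouring sequence, or the replicates against each other. Read numbers are not given in the sources used here, so the depth of each replicate is unknown. Signal values describe and rank peaks within a list, and were set side by side between replicates only at matched peaks. All intervals are 95% intervals and cover counting error over peaks or genes, which are not independent replicates.

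The optimal list, which the depositors made with the irreproducible discovery rate (IDR) from both replicates, held 44058 peaks on mm10. The stricter conservative list held 35879, of which 31856 were the same intervals as in the optimal list. Relaxed lists held 215095 peaks for replicate 1, 300000 for replicate 2 and 300000 for both replicates pooled. A separate list on mm9 held 27671 peaks. Chromosome 11 carried 38.1 optimal peaks per Mb and chromosome 16 carried 22.6, against 21.4 on chromosome 19, 12.7 to 18.9 on the other autosomes and 3.49 on chromosome X. Chromosome 11 alone held 10.6% of the optimal peaks.

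**Figure D1:**
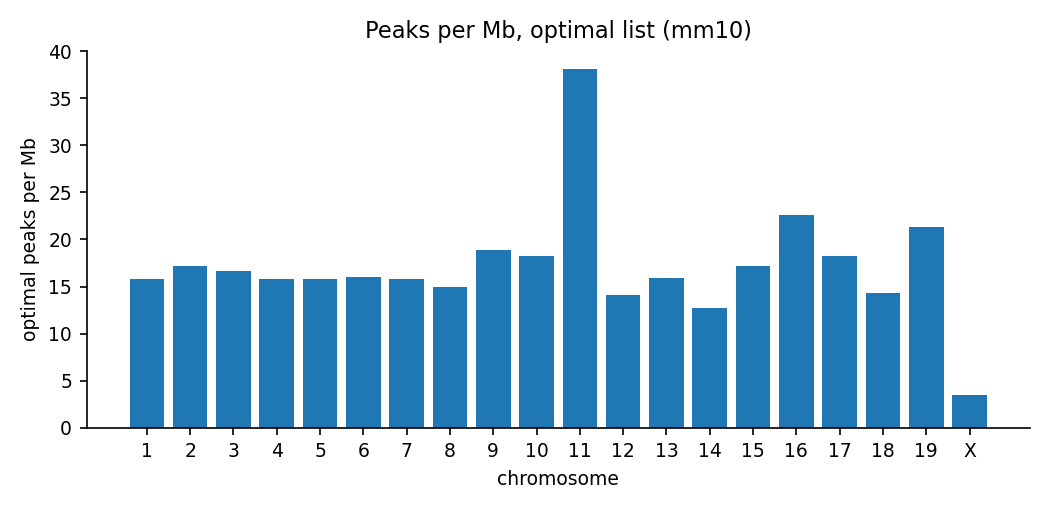
Optimal peaks per Mb (y axis) on each chromosome of mm10 (x axis), 1 bar per chromosome. Chromosome 11 reaches 38.1 peaks per Mb, chromosome 16 reaches 22.6 and chromosome X 3.49.

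The strongest peaks lay mostly inside genes and away from their starts. The highest peak was in Ptger3, a prostaglandin E receptor gene (chromosome 3, 157635759 to 157636022, mm10), with a pooled signal of 480.4 and a signal of 235.7 in replicate 1 and 245.0 in replicate 2. The next lay within Zbtb20, a zinc finger repressor gene (chromosome 16, 43383164 to 43383540, signal 469.7), although the nearest annotated gene start was that of Tigit, 281742 bp away. Peaks within Rab37 (468.7), Ppa2 (465.2), Enpp6 (450.4), Recql5 (448.9), Tbc1d10a (445.2) and Snx29 (436.8) were also among the 10 strongest. The remaining pair lay in Vps8, with 2510009E07Rik as the gene of the nearest start (456.5), and between genes, 113689 bp from the start of Mrpl39 (446.7). All 10 had a matched peak in both replicates. The peaks at Rab37, Recql5 and Tbc1d10a lay on chromosome 11, and those at Zbtb20, Vps8, Mrpl39 and Snx29 on chromosome 16. These are the chromosomes with most peaks per Mb, and whether extra copies of them raise the signal there stays open. Foxp1, which encodes a forkhead factor needed for B-cell development, had the most optimal summits from 10 kb upstream to 10 kb downstream (64). It was followed by Zbtb20 (59), Ebf1, the gene of an early B-cell factor (47), Msi2 (46) and Atxn1 (44). These are long genes, and per 100 kb the values were 10.4 for Foxp1, 7.58 for Zbtb20, 11.46 for Ebf1, 11.53 for Msi2 and 10.1 for Atxn1. The shorter gene Cd86, with 32 summits, had 27.3 per 100 kb. Of these genes, Ebf1 and Msi2 lie on chromosome 11, and Zbtb20 and Cd86 on chromosome 16.

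How far the replicates gave the same sites was asked first. Of the 44058 strongest peaks of replicate 1, 64.1% (63.6 to 64.5) had a summit within 100 bp of one of the 44058 strongest of replicate 2, against 0.392% when peaks were shifted along their chromosomes. Among the 5000 strongest the share was 82.0%. Of the replicate 1 peaks, 828 had no summit within 500 bp in the whole replicate 2 list of 300000 peaks. Of the replicate 2 peaks, 2081 had none in the whole replicate 1 list of 215095. Their median ranks were 37358 and 35114. These lists are relaxed and differ in length, and no shifted level was computed for this count, so it does not measure agreement. Optimal peaks were matched to the nearest summit of each replicate within 100 bp, whatever its strength. Across the 37635 optimal peaks matched in both replicates, signal values had a Spearman correlation of 0.717, with no p-value because peaks are not independent. The optimal list was made by IDR from the same replicates and only matched peaks enter, so this value does not measure agreement over all peaks. The log2 ratio of replicate 2 to replicate 1 had a median of 0.533 over these peaks, so replicate 2 values mostly ran higher, which bears on each pair of replicate signals given here. Its SD was 0.41 in the strongest quartile of peaks and 0.81 in the weakest.

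Some strong sites stood far apart in the ranking of the replicates by their matched summits. The nearest summit of each replicate was taken, even where a stronger one lay close by. These differences therefore need not be differences in binding. Ranks here were counted among the 37635 matched optimal peaks only, by the signal of each replicate, and are not ranks in the relaxed lists. Among the 10919 matched peaks in the strongest quartile the median rank difference was 1408, and the largest differences were taken 5 each way. Peaks nearest to Lmo4, Gm13420, Slc11a1, Cluh and She ranked higher in replicate 2. The Lmo4 peak (chromosome 3, 144138716 to 144139055, mm10) ranked 36842 in replicate 1 and 4564 in replicate 2, with signals of 5.98 and 67.9. Peaks nearest to Igsf5, Inpp5d, Dnajb12, 2510009E07Rik and Btbd11 ranked higher in replicate 1. The peak in Inpp5d, the gene of the phosphatase SHIP1 (chromosome 1, 87621901 to 87622240, mm10), ranked 3506 in replicate 1 and 25546 in replicate 2, with signals of 55.1 and 20.9.

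Summits lay at promoters more often than chance placement gives, yet the strongest sites were mostly elsewhere. Random placement does not separate binding from signal at promoters in general. Of the optimal summits on chromosomes 1 to 19 and X, 17.5% (17.1 to 17.8) lay within 1 kb of the start of a protein-coding gene, against 1.63% of random positions, 10.7 times as many. The ratio was 17.2 within 500 bp, 5.90 within 2500 bp and 6.60 on the mm9 list with all transcripts. A further 20.9% lay 1 to 10 kb away, 46.8% lay 10 to 100 kb away and 14.9% lay farther. The median distance was 18930 bp, against 73151 bp for random positions. In the mm9 list, where transcripts could be used, 39.9% of summits were in introns against 35.9% of random positions, 41.6% were intergenic against 59.4%, 1.29% were in untranslated regions against 1.09%, and 1.15% were in coding exons against 1.19%.

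The promoter share was lower among strong peaks. It was 10.2% (9.65 to 10.8) in the strongest quartile of optimal peaks and 21.3% (20.5 to 22.0) in the weakest, an odds ratio of 0.421 (0.390 to 0.454, two-sided Fisher's exact test, p = 3.2e-114). The change was not even along the signal range: the share was 5.88% in the strongest decile and 11.2% in the next, between 17.3% and 19.8% in the deciles from the third to the ninth, and 26.8% in the weakest. The weak end of the optimal list included peaks beside stronger ones. Of its 1414 peaks ranked past 100000 in the pooled list, 37.7% lay within 340 bp of a summit of the 30000 strongest pooled peaks. Of all pooled peaks past that rank, 0.708% did. Among optimal peaks within the top ranks of the pooled list the weakest quartile had 18.1% at promoters and the strongest 9.21%. Peaks of the optimal list that were absent from the conservative list were at promoters more often (20.8%) than peaks in both (16.2%, exact p = 2.8e-29). Peaks found in replicate 2 with no summit near in replicate 1 were at promoters less often (11.1%) than peaks shared by both replicates (14.9%, exact p = 1.4e-06). For peaks of replicate 1 alone the share was 15.2%, with no detectable difference from shared peaks (exact p = 0.80).

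**Figure D2:**
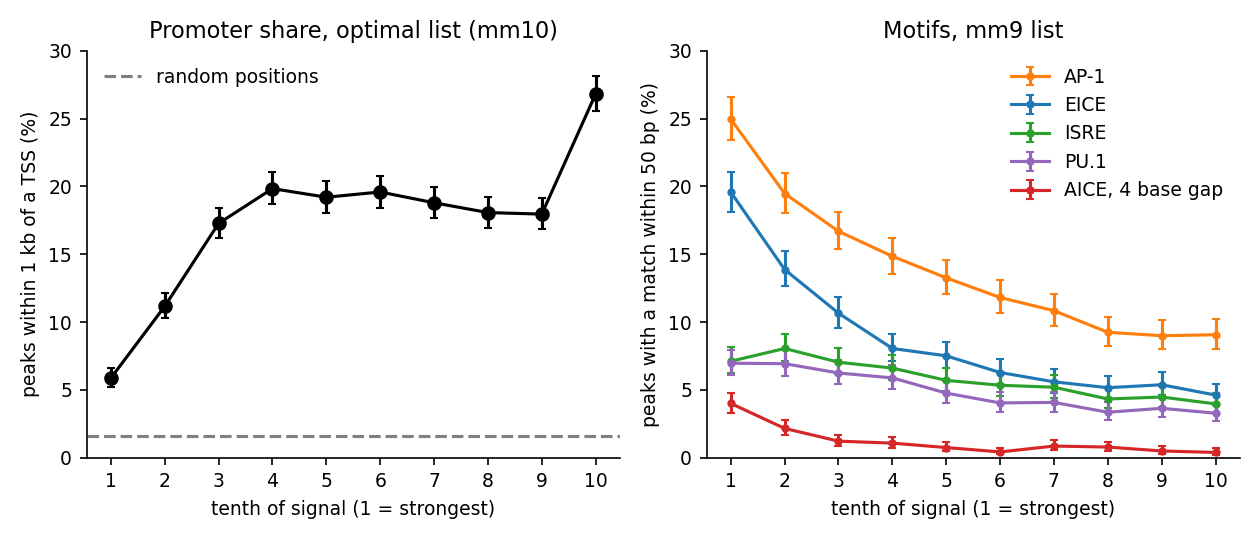
Left, percent of optimal peaks within 1 kb of a gene start (y axis) by decile of signal (x axis, 1 is the strongest), with random positions as a dashed line; right, percent of mm9 peaks with a motif within 50 bp of the summit. Points are shares with 95% Wilson intervals; the promoter share is 5.88% in the strongest and 26.8% in the weakest decile with a flat middle, and EICE goes from 19.6% to 4.63%.

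Which sequences lay under the summits was asked on the mm9 list. IRF4 binds DNA weakly alone and occupies composite elements with partner factors. The ETS-IRF composite element (EICE, GGAANNGAAA), where IRF4 pairs with PU.1 or Spi-B, was within 50 bp of 8.68% (8.35 to 9.01) of summits, against 0.965% of windows 300 bp away, 8.99 times as many. The ratio was 13.8 with windows of 25 bp either side and 5.08 with 100 bp. The AP-1-IRF composite elements (AICE), bound with BATF and JUN proteins, were rarer but more concentrated. The form with adjoining sites was at 1.19% of summits against 0.0434%, and the form with a gap of 4 bases at 1.23% against 0.0253%. The IRF-IRF element ISRE was at 5.79% against 1.43%, the AP-1 site, inside or outside an AICE, at 13.9% against 1.72%, and the PU.1 site at 4.93% against 0.661%.

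Sites of several other factors were also more frequent at summits than beside them. They included the Oct octamer (2.61% against 0.593%), EBF1 (1.15% against 0.188%), RUNX (3.89% against 1.06%), NF-kB (7.02% against 1.80%), MEF2 (0.441% against 0.224%), the CAGCTG E-box (8.72% against 4.69%) and the SP/KLF site (0.972% against 0.614%). CTCF, included as a comparison motif, was at 2.36% against 0.0542%. The GATA site of other blood lineages was less frequent at summits (0.426% against 0.748%, exact McNemar test, adjusted exact p = 1.3e-06), as was the NFY site (2.74% against 3.17%, adjusted exact p = 0.0035). For HNF4 (adjusted exact p = 0.24) and REST (adjusted exact p = 0.52) no difference was detectable. EICE read backwards, with the same bases, was at 0.922% of summits and 0.976% of flanks (adjusted exact p = 0.54), whereas ISRE read backwards was at 2.36% against 1.53% (adjusted exact p = 2.8e-12) and the AICE with a gap of 4 bases read backwards at 0.0759% against 0.0289% (adjusted exact p = 0.029). The lower GATA share was not past the threshold against shuffled windows, the NFY difference turned with windows of 100 bp, and the MEF2 excess was not past it with windows of 25 bp. The excess of that backwards AICE was not past it with windows of 25 bp or against shuffled windows, and with windows of 100 bp the REST motif and the adjoining AICE read backwards passed it. The adjusted p-values cover 22 motifs; those of EICE and AP-1 were too small for the software to represent.

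**Figure D3:**
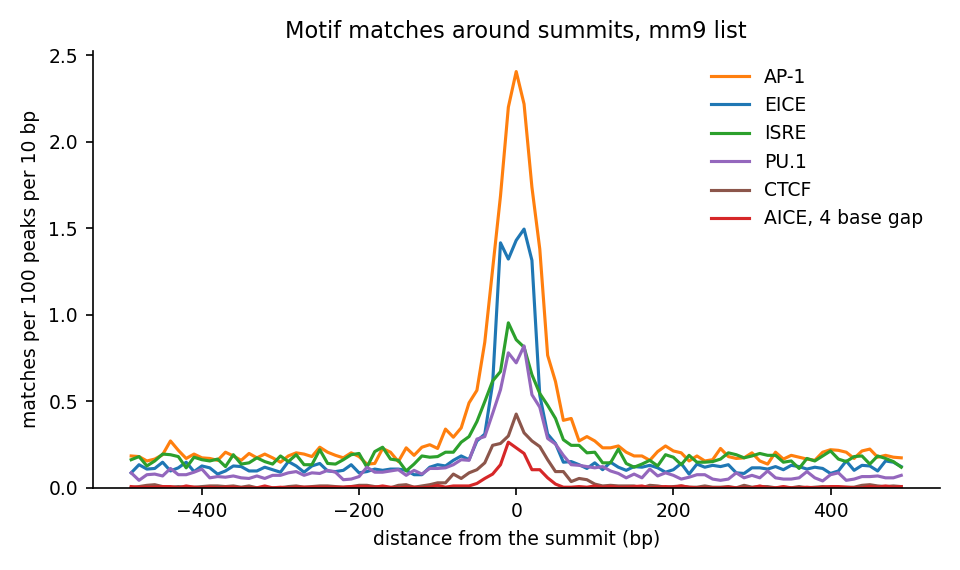
Motif matches per 100 peaks per 10 bp (y axis) by distance from the summit in bp (x axis) in the mm9 list, 1 line per motif. Each motif shown has its maximum within 20 bp of the summit, and the median distance of EICE matches within the window was 15.5 bp.

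The spacing of the ETS and IRF sites had a single high value. GGAA followed by GAAA with 2 bases between them was in 2401 summit windows and 267 flank windows, while a gap of 3 bases gave 583 against 238 and a gap of 1 base gave no excess. The 2 bases between them were GT in 32.3% of the matches at summits and CT in 25.3%, against 3.22% and 3.86% in the flanks. The opposite order, GAAA then GGAA with the same gap, was in 1134 summit windows against 260. GAAA directly before an AP-1 site was in 275 against 4, and TTTC with a gap of 4 bases before it in 256 against 5. AP-1 sites are themselves more frequent at summits, and every gap searched for these pairs exceeded the flanks. The excess alone therefore shows no preferred spacing. The next highest counts were 114 against 6 for GAAA at a gap of 3 bases and 149 against 11 for TTTC at a gap of 6. A search over all words of 8 bases put GGAAGTGA first (6.78% of peaks at the summit only, 0.542% in the flank only), then AAGTGAAA. Both words fit inside an EICE, but neither is confined to it. GGAAGTGA was at the summit only in 1875 peaks, while EICE matches with GT between the sites numbered 788. In the strongest decile without an IRF element or AP-1 site, GGAAGTGA was in 108 peaks at the summit only and in 3 in the flank only. At promoters the first was ACTTCCGG, an ETS site (5.40% against 0.474%).

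**Figure D4:**
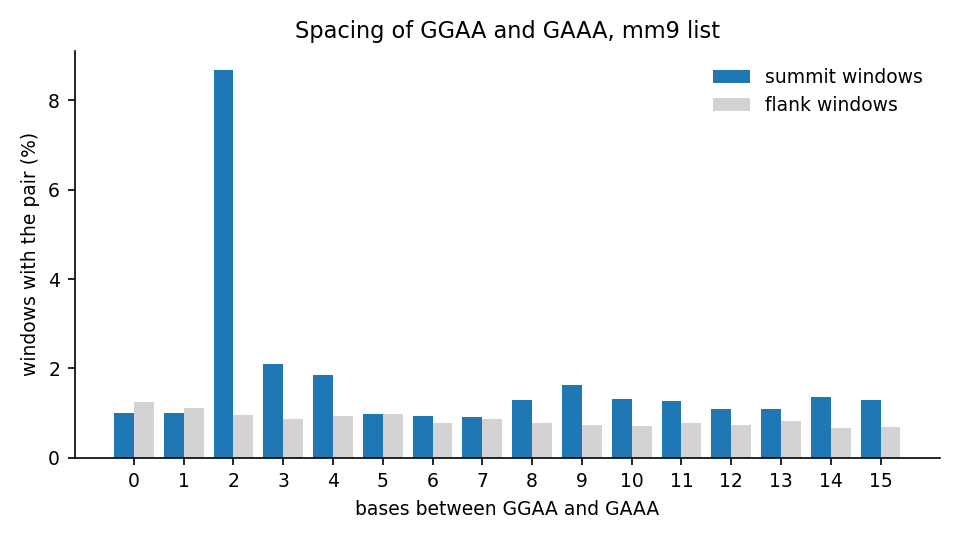
Percent of windows with GGAA followed by GAAA on the same strand (y axis) by the number of bases between them (x axis), for summit windows in blue and flank windows in grey. The gap of 2 bases stands out with 8.68% against 0.965%.

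The composite elements were concentrated in the strongest peaks. EICE was at 15.8% (14.9 to 16.6) of the strongest quartile and 5.0% (4.51 to 5.54) of the weakest, an odds ratio of 3.55 (3.13 to 4.03, Fisher's exact test, adjusted exact p = 1.0e-98 over 6 motifs). The AICE with a gap of 4 bases had the largest odds ratio of the 6 motifs, 5.09 (2.73% against 0.549%); below EICE came the adjoining AICE with 3.16, AP-1 with 2.69, PU.1 with 2.03 and ISRE with 1.82. At least 1 of the 4 IRF elements was at 26.6% of the strongest quartile and at 16.2% of all summits, so 83.8% of peaks held none in the form searched. In the strongest decile 68.3% held none. Among peaks of that decile without an IRF element or AP-1 site, the leading word was AGAAGTGA (9.18% against 0.359%), which differs from the EICE pattern searched.

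Promoter peaks held fewer of these elements than distal peaks. EICE was at 4.92% (4.32 to 5.60) of peaks within 1 kb of a gene start and 9.61% (9.18 to 10.1) of peaks over 10 kb away (odds ratio 0.487, 0.421 to 0.563, adjusted exact p = 4.4e-25), and AP-1 was at 5.01% against 16.3% (odds ratio 0.272, adjusted exact p = 2.4e-98). For ISRE the odds ratio was 0.610 and for PU.1 0.583. In the strongest quartile EICE was at 15.98% of promoter and 15.4% of distal peaks, and in the weakest at 1.79% and 5.90%; whether the difference itself changed with signal was not tested. Promoter windows had a mean GC content of 59.2% and distal windows 47.7%. Compared within deciles of the GC content of the window, which includes the motif itself, the EICE odds ratio was 0.932 (0.795 to 1.09), so that call ended because the odds ratio moved towards 1, and with the GC content of the sequence beside the window it was 0.828 (0.699 to 0.980). The ISRE odds ratio turned to 1.43 (1.19 to 1.72) within deciles of window GC content but was 1.06 (0.870 to 1.28) with that of the sequence beside it. Within deciles of window GC content the AP-1 odds ratio was 0.480 (0.413 to 0.559). The adjoining AICE, with a crude odds ratio of 0.298, was not past the threshold with window GC content (0.698, 0.428 to 1.14) or with that beside it (0.621, 0.373 to 1.04). The AICE with a gap of 4 bases stayed low in both (0.383, 0.203 to 0.723, and 0.380, 0.200 to 0.721).

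Which gene groups lay near summits was tested with 23 gene lists. Of 20564 protein-coding genes, 51.2% had an optimal summit within 10 kb of the start, and 18 lists exceeded the other genes (two-sided Fisher's exact test, adjusted over the 23 lists) while 1 fell below them. All 16 genes of the list of IRF4 targets in B cells had a summit (adjusted exact p = 1.2e-04). The strongest was 9124 bp upstream of Il10, which encodes an anti-inflammatory cytokine (chromosome 1, 131010500 to 131010857, mm10), with a pooled signal of 326.8 and 158.5 and 165.6 in replicates 1 and 2. Ikzf3 followed with 279.6, then Xbp1, a regulator of plasma cell secretion, with 202.4, Ciita, the master regulator of MHC class II, with 197.0, and Spib, the gene of an ETS partner, with 194.6. Lower signals were found at Cd40 (116.9), Pax5 (111.2), Ebf1 (96.4), Myc (70.0), Ikzf1 (67.3), Bcl6 (49.2) and Zbtb46 (45.0). Irf4 itself had a summit 20 bp from its start (chromosome 13, 30749083 to 30749422, mm10), with a pooled signal of 46.8 and signals of 11.7 in replicate 1 and 38.6 in replicate 2. The summits within 10 kb of Prdm1, the gene of the plasma cell regulator Blimp-1 (46.1), and of Irf8 (23.3) were absent from the conservative list. Prdm1 had 19 optimal summits from 10 kb upstream to 10 kb downstream of the gene.

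The groups of B-cell function followed. All 20 antigen presentation genes had a summit (adjusted exact p = 1.2e-05), led by a shared peak near Psmb9 and Tap1 (333.1), Cd74, the MHC class II invariant chain (231.1, 119 bp upstream), and H2-DMb2 (229.7, 49 bp upstream). Of the cytokine signalling genes 26 of 27 had one (adjusted exact p = 5.6e-06), among them Il21r (346.5), the BAFF receptor gene Tnfrsf13c (338.1), Il6ra (333.1) and Il10, and all 27 did without replicate 1. Of the B-cell receptor signalling genes 24 of 25 did (adjusted exact p = 1.2e-05), with Syk (352.9), Cd79b (274.2), Blnk (227.5) and Pik3cd (190.1), and 23 did without replicate 2. Of the B lineage identity genes 20 of 21 did (adjusted exact p = 1.1e-04), including Blk (225.0), and all 21 did without replicate 2. Of the trafficking genes 18 of 19 did (adjusted exact p = 2.7e-04), with Cxcr5 (213.6), Ccr7 (201.4), Itgal (159.3) and Cxcr4 (119.0), although not at 50 kb (odds ratio 5.98), and of the NF-kB pathway genes 18 of 20 (adjusted exact p = 0.0012), with Rel (294.6), Nfkbia (269.6), Traf1 (227.4) and Traf2 (138.7). The settings without a replicate used the strongest peaks of the other replicate's relaxed list, as many as in the optimal list. Those peaks had not passed IDR, so the kind of list differs as well as the samples. Leaving out either replicate in this way gave 20 of 20 NF-kB genes. The odds ratio of 8.58 was 36.4 without replicate 1 and 38.96 without replicate 2. Where all genes of a list had a summit, the odds ratio carries the continuity correction. The odds ratio of the receptor genes went from 22.9 to 10.9 and that of the lineage genes from 19.1 to 40.9 without replicate 2, and that of the cytokine genes from 24.8 to 48.9 without replicate 1.

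Plasma cell, germinal centre and interferon-stimulated genes and the factor families also exceeded the other genes. Of the plasma cell genes 16 of 20 had a summit (adjusted exact p = 0.018), with Sec11c (315.7), Xbp1, Derl3 (192.3) and Tnfrsf13b (185.9). The plasma cell odds ratio of 3.81 was 2.52 at 1 kb and 1.88 at 50 kb, where the call ended. Of the germinal centre genes 14 of 17 did (adjusted exact p = 0.018), with Foxo1 (271.4), Mef2b (225.6) and Rgs13 (99.4). Their odds ratio of 4.45 was 2.13 without replicate 1, 2.32 at 1 kb and 5.32 at 50 kb, and the call ended in each. Of the interferon-stimulated genes 22 of 28 did (adjusted exact p = 0.0076), and their strongest peaks lay at the gene start: 5 bp upstream of Irgm1 (283.3), 21 bp upstream of Trim25 (223.0), 106 bp upstream of Ifit1 (197.2) and 533 bp downstream of that of Gbp3 (322.9). Of the IRF family 8 of 9 had one (exact test, adjusted exact p = 0.048), with Irf5 (198.5), Irf1 (189.6), Irf2 (151.2) and Irf9 (124.8). The odds ratio of the family was 7.62, and its call ended in 6 of 8 alternatives: without replicate 1 (7.10), on the conservative list (4.23), at 50 kb (6.31), on the mm9 list (3.59) and against lists matched on CpG content (4.91) or gene density (7.06). Of the ETS and AP-1 partners 14 of 17 did (adjusted exact p = 0.018), with Junb (224.4), Spib, Fosl2 (175.9) and Jund (133.0). Their odds ratio of 4.45 was 2.95 at 1 kb and 3.56 against CpG-matched lists, where the call ended, and 15.2 without replicate 2.

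General cell functions also exceeded the other genes. Of the ribosomal protein genes 37 of 39 had a summit (adjusted exact p = 8.8e-08), with signals of 126.9 at Rps9, 87.7 at Rpl23, 85.7 at Rps20 and 80.3 at Rpl27. The ribosomal odds ratio of 17.7 was 6.47 without replicate 2, and on the mm9 list 16 of 39 had a summit, with an odds ratio of 1.247 that ended the call. Of the apoptosis genes 17 of 20 did (adjusted exact p = 0.0057), with Mcl1 (171.1), Casp8 (169.5), Bid (146.6) and Bcl2l11 (137.8). The apoptosis odds ratio of 5.40 was 1.69 at 1 kb and 2.99 at 50 kb, where the call ended, and 3.55 without replicate 1. Of the cell cycle genes 24 of 29 did (adjusted exact p = 0.0015), with Rb1 (240.9), E2f2 (104.5), Ccnd3 (74.2) and E2f3 (71.0), a call that ended against CpG-matched lists (odds ratio 2.55). Of the unfolded protein response genes 19 of 22 did (adjusted exact p = 0.0021), with Xbp1, Hsp90b1 (162.6), Atf6 (159.3) and Dnajb9 (100.4). Their odds ratio of 6.04 was 18.7 without replicate 1, 9.50 without replicate 2 and 2.94 against CpG-matched lists, where the call ended. Of the oxidative phosphorylation genes 21 of 28 did (adjusted exact p = 0.018), with Ndufa2 (181.0), Ndufa9 (84.9), Ndufs3 (76.2) and Atp5d (67.9). Their odds ratio of 2.86 was 2.18 on the conservative list, 2.06 at 1 kb, 1.55 on the mm9 list and 1.48 against CpG-matched lists, and the call ended in each.

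Among the lists of other cell types, 21 of 27 T-cell genes had a summit (adjusted exact p = 0.011), with Ctla4 (353.1), Lck (226.7) and Cd2 (175.6). Within 1 kb of the start the T-cell odds ratio was 0.588 (adjusted exact p = 0.32), and at 50 kb it was 4.16 and not past the threshold. The myeloid genes, 12 of 22 with Cebpb (165.8) and Cd68 (134.4), did not pass the test (adjusted exact p = 0.87), but they exceeded the other genes at 50 kb (odds ratio 6.98) and on the mm9 list (2.59). Neither did the erythroid and megakaryocyte genes, 9 of 18 with Itga2b (149.6) and Gp1ba (88.8, adjusted exact p = 1.0), nor the liver genes, 8 of 24 with Ahsg (56.8) and Apoa1 (53.1, adjusted exact p = 0.12), although the liver genes fell below the others at 1 kb, with 0 of 24 (odds ratio 0.0420), and without replicate 1 (0.365). The genes of class switching and mutation had 15 of 23 (adjusted exact p = 0.23), with Apex1 (143.6). Neuron genes fell below the other genes, with 7 of 26 (adjusted exact p = 0.022), among them Camk2a (86.4), Gad1 (45.0), Dlg4 (44.5) and Tubb3 (42.7). Against 10000 random lists matched on the CpG content of the gene start, 13 lists were higher by permutation test. The neuron call ended on the mm9 list (odds ratio 0.426) and against lists matched on gene density (0.406).

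**Figure D5:**
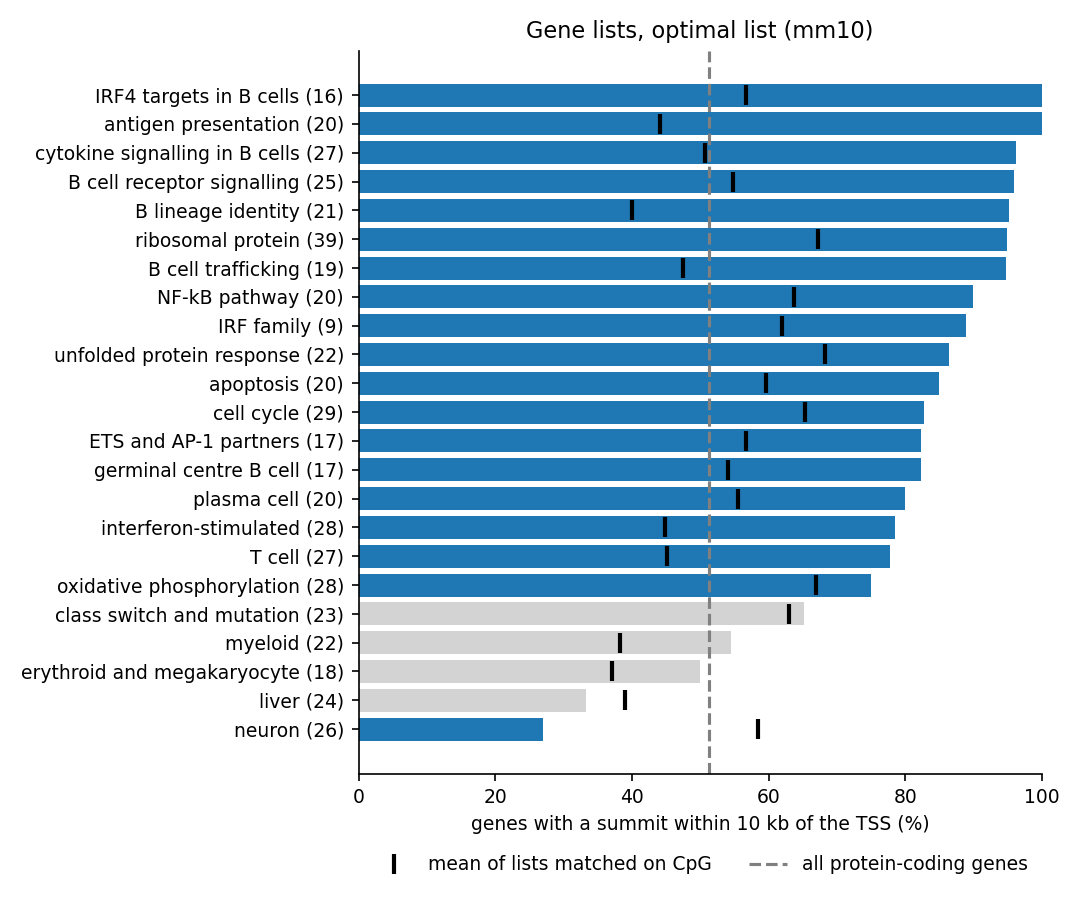
Percent of each list's genes with an optimal summit within 10 kb of the start (x axis), with the number of genes in brackets; blue bars have an adjusted p under 0.05 in either direction. The dashed line is all protein-coding genes (51.2%) and the ticks are means of lists matched on CpG content; neuron genes lie lowest at 26.9%.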

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

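The peaks on scaffolds entered the list sizes and the comparison of replicates but none of the location, motif or gene list comparisons. The optimal list has 11 peaks on unplaced or unlocalised scaffolds of mm10, above the 3 that a count of 0 allows. Of these, 6 lie on the unplaced scaffold Un_JH584304, with a signal of up to 150.9. No explanation was tested.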

How the results depend on the processing

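The stratification by GC content, the mm9 list as an alternative peak set, the optimal peaks restricted to the pooled top ranks and the overlap of the 1000 strongest peaks were chosen after seeing the data; the others were fixed before. The promoter share stayed above random positions and the strong against weak difference stayed below 1 under all 7 alternatives run for each, including each replicate alone. The count of motifs more frequent at summits and the count of gene lists above other genes stayed within 1.5 times under all 3 and all 8 alternatives. The EICE difference between strong and weak peaks held under all 4.

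Replicate overlap depended on its definition. It was 72.6% with 1 shared base, 65.7% with reciprocal overlap of the larger part of each interval, 53.7% with summits within 50 bp, 66.4% for the size of the conservative list, 77.8% for the 10000 strongest, 82.0% for 5000 and 81.0% for 1000. The signal correlation was 0.777 on the conservative list and 0.674 with 1 shared base. The optimal list has 22029 peaks at or above its median signal and 28594 with a score of at least 2.

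Within GC deciles of the window, which includes the motif, the EICE odds ratio of promoter against distal peaks was 0.932, no longer past the threshold, and that of ISRE turned to 1.43; within GC deciles of the sequence beside the window they were 0.828 (0.699 to 0.980) and 1.06. With windows of 100 bp the differences of NFY (0.0723 percentage points), HNF4 (0.00361) and EICE read backwards (0.0108) turned positive without passing the test, and the last was 0.0289 against shuffled windows; the cause was not tested.

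Single gene lists, those without a call included, kept their direction and their side of the threshold in 149 of the settings run, lost a call in 26, gained one in 4 and turned direction in 5. The odds ratios that turned were T cell (0.588) and myeloid (0.325) at 1 kb, erythroid and megakaryocyte at 50 kb (1.66) and against CpG-matched lists (1.69), and myeloid against density-matched lists (0.971). On the mm9 list the ribosomal protein odds ratio was 1.247, not past the threshold. Motif tests on the conservative and single-replicate lists, the comparisons of motifs between conservative and optimal-only peaks and between shared and single-replicate peaks, and the repeat-masked alternative were not run, since they need mm10 or masked sequence, which was not used here. No paired analysis was possible because there is 1 group. The unknown depth limits what can be said of weak peaks.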

Other observations

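The tests of the CTCF pattern, the base composition test of EICE, the word search and the EICE share by chromosome were chosen after the result was seen; the tests of the chromosomes and the signal test of EICE at promoters were set down before their results, although the patterns had been seen.

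At all promoter peaks of the mm9 list, the ETS word ACTTCCGG led, at 5.40% of summits only against 0.474% of flanks only. GGAAGTGA, which fits inside an EICE, ranked 3 with 4.95% against 0.678%. Promoter peaks without an IRF element, from which EICE matches had been removed, were searched as well. There ACTTCCGG was at 5.65% against 0.496%, and the CRE palindrome TGACGTCA at 2.18% against 0.174%. EICE and either AICE occurred together at 20 of 27671 summits, while EICE alone or with others was at 2401 and either AICE at 660.

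Chromosomes 11 and 16 held more peaks than other autosomes, with 2.32 (2.00 to 2.66) and 1.39 (1.12 to 1.65) times as many optimal peaks per 1 Mb bin, by bootstrap over bins. The tables argue against gene density as the whole cause: in bins with equal numbers of gene starts the ratios were 1.80 (1.63 to 1.97) and 1.54 (1.29 to 1.81). Extra copies of these chromosomes in the line may raise background and peaks alike. Weak pooled peaks outside the optimal list were also 2.33 and 1.64 times as many, but in bins without a gene start the ratios were 1.55 (0.768 to 2.77) on 11 bins and 1.17 (0.761 to 1.71) on 20 bins, so extra copies stay open.

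A CTCF motif lay within 50 bp of 652 mm9 summits, with a median distance of 18.5 bp, in 0.506% of the strongest and 4.12% of the weakest quartile. The tables argue against an IRF element beside the CTCF motif, since these peaks held one less often than others (2.61% against 16.5%, odds ratio 0.135, 0.0836 to 0.220). They also argue against signal at promoters in general, since these peaks were at promoters less often (odds ratio 0.448, 0.337 to 0.596). Indirect capture of CTCF-bound DNA and open chromatin remain untested, and no biological explanation was tested.

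EICE was less frequent at promoter peaks. Their weaker signal is not the whole cause: within deciles of signal the odds ratio was 0.595 (0.514 to 0.690). That value pools all deciles and does not describe the strong peaks. In the strongest quartile EICE was at 15.98% of promoter and 15.4% of distal peaks, and in the weakest at 1.79% and 5.90%. The base composition of promoters may account for part of the difference: within deciles of the GC content beside the window the odds ratio was 0.828 (0.699 to 0.980). That interval excludes equal odds, so a smaller difference remained within these deciles, and base composition was not shown to be the whole cause. Signal and the GC content beside the window were not held equal together, so their joint share is unknown. The GC content of the window itself gave 0.932 (0.795 to 1.09), and together with deciles of signal 1.02 (0.868 to 1.20). That window includes the motif, so these values decide nothing.

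EICE was at 6.90% of mm9 peaks on chromosomes 11 and 16 and at 9.03% of those elsewhere (Fisher's exact test, p = 1.5e-06). The chromosomes were picked for their number of peaks, and the test counts peaks as independent. Location, signal and GC content were not held equal, so the difference is descriptive.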
